A study of Mus musculus with 4 samples.

How the data were processed

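Marrow of 4 chimeric mice, 2 per group, was measured as 1 pooled single-cell library per mouse. The deposited matrices hold raw UMI counts per gene and barcode for all barcodes, empty droplets included, made with Cell Ranger 4.0.0 on GRCm38/mm10 per the submitters' processing notes, which also name Seurat. The values were checked to be whole numbers, and 27645 of 27998 features (98.7%) matched GENCODE vM21. Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, giving 16280 cells. These held 87.3%, 86.4%, 87.9% and 87.3% of the UMIs of Idh1-WT 1 and 2 and Idh1-R132H 1 and 2, and came to 37.5%, 29.2%, 32.0% and 36.9% of the cells sorted. Scrublet in scanpy called 18 doublets (0.111%), far below the expected share, so its automatic threshold did not separate doublets. These 18 were removed, leaving 16262 cells, and removal of the 534 top-scoring cells was added as an alternative.

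Cells of the 4 libraries were clustered together without integration (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1, random seed 1). Clusters were named from 18 marker sets. Clusters with a relative UMI count below 0.1 or a mean doublet score above 0.15 stayed unnamed. A cluster took its second-scoring class if that class had at least 5 markers among the 10 leading genes, and more than the first. These limits were set after the clusters were seen. The unnamed clusters held 10.2%, 2.80%, 3.18% and 3.64% of the cells of Idh1-WT 1 and 2 and Idh1-R132H 1 and 2. Assigning each cell by its markers alone gave the same class for 55.0% of stem and multipotent progenitor-like cells, 78.6% of granulocyte-monocyte progenitor-like cells and between 75.3% and 97.6% of the others.

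Raw counts were summed per library and class, for classes with at least 20 cells in every library. Genes passing filterByExpr were tested with edgeR's quasi-likelihood test (TMM, robust) at a Benjamini-Hochberg FDR of 0.05, and again with DESeq2. Shares were tested with edgeR on cell numbers, and exact permutation was run beside it. The 29 gene lists were tested with camera in limma at a preset correlation of 0.01 and again with the correlation estimated. With 2 libraries per group the estimated setting tests on few degrees of freedom, so hardly any list could pass there. Differences of effect between adjacent classes used a genotype by class term with the library as a block. The marker sets, gene lists, filters, comparisons and the rule for named genes were fixed before the data were examined. By that rule, each class names the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 5, up to 4 members of each list with the smallest p, and 10 fixed genes. Other changed genes named in the text were chosen after their values were seen, as were the Irf8 and F13a1 progenitor cluster and the lymphoid-primed, T or NK-, basophil or mast- and dendritic cell-like classes. Where no counts were seen in a group, the bound uses a floor of 3 counts over the group. Intervals and floors of counts cover counting error only. For each called gene the cells carrying it were counted, and the share of its UMIs in the 5 richest cells of the group with the higher level is given for named genes in which it exceeded that of all other cells of the group, a check added after the data were seen.

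The alternatives were UMI minimums of 300 and 1000, at most 5% mitochondrial UMIs, doublet calls kept, resolution 2, a class per cell, RLE factors, library totals, DESeq2, no filter, subtraction of free RNA, equal cell numbers, a replicate block and each library left out in turn. With 1 library left out, the lone library of a group is assumed to vary like the other group. Free RNA was taken from barcodes with at most 50 UMIs. Its share came from S100a8 and S100a9 in mature B-like cells only, because immunoglobulin genes are not among the features, and was 229, 165, 231 and 210 UMIs per mature B-like cell in Idh1-WT 1 and 2 and Idh1-R132H 1 and 2. The same genes in T or NK-like cells gave 573, 243, 258 and 313 UMIs per cell, an estimate used as a second setting for the tests of free RNA and added after the data were seen. Removal of top-scoring doublets, low-UMI clusters kept and Xist-carrying cells alone (with a Xist UMI and no UMI of a Y-linked gene) were added after the data were seen.

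The gene test was tested on simulated data with 200 changed genes per comparison. At a log2 fold of 0.5 it recovered 52.2% in stem and multipotent progenitor-, 56.7% in granulocyte-monocyte progenitor-, 17.2% in neutrophil precursor-, 14.5% in neutrophil-, 19.4% in monocyte-, 7.69% in erythroid progenitor-, 12.9% in mature B- and 23.1% in megakaryocyte progenitor-like cells and 61.2% in all cells summed. At a log2 fold of 1 the values were 76.1%, 86.4%, 62.9%, 55.7%, 59.7%, 51.6%, 43.6%, 62.5% and 86.4%, and at 2 they were 100%, 98.5%, 90.6%, 96.7%, 93.7%, 100%, 85.5%, 96.8% and 96.9%. In the Irf8 and F13a1 progenitor cluster and the lymphoid-primed, T or NK-, basophil or mast- and dendritic cell-like classes, 50.0%, 15.9%, 11.7%, 28.1% and 10.9% were recovered at 0.5, 84.8%, 56.9%, 41.7%, 60.7% and 54.7% at 1, and 98.4%, 89.1%, 84.5%, 100% and 96.4% at 2. False calls made up between 0% and 10.8% of the calls. The genotype by class term was simulated only at a log2 difference of 2, between neutrophil precursor- and neutrophil-like cells, and recovered 181 of 200 genes with 7 false calls. Its changed genes were drawn from the most abundant genes, with a fixed dispersion and no library effect. The gene test was simulated with trended dispersions, without gene-specific variation. The libraries may vary more than these simulated data. A simulated halving of the neutrophil share was recovered in 94 of 100 draws with 16 false calls. That simulation held 14 classes without the unnamed cells, with a fixed variation between libraries. The test of shares of all classes held 15, with the unnamed cells at 10.2% and 2.80% in Idh1-WT 1 and 2. Its recovery may therefore be lower.

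Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, scanpy 1.11.5, anndata 0.12.19, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.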

Results

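The series profiled mouse bone marrow by single-cell RNA sequencing in 4 libraries, 2 labelled Idh1-WT and 2 labelled Idh1-R132H. Idh1 encodes the cytosolic NADP-dependent isocitrate dehydrogenase, and the R132H change gives the enzyme the ability to make 2-hydroxyglutarate, which inhibits 2-oxoglutarate-dependent dioxygenases. Recombination of the EYFP reporter and of the heterozygous mutant allele was induced with tamoxifen for 5 days. EYFP-positive lineage-negative marrow cells were taken 2 weeks later and transplanted into irradiated mice, and chimeric marrow was collected 16 weeks after transplantation. From each mouse, 4000 cells of each of 3 sorted populations were pooled before 3′ library preparation: total CD45.1-positive cells, LSK cells (lineage-negative, Sca1-positive, cKit-positive) and LK cells (lineage-negative, cKit-positive). The title of the series places the question in the production of neutrophils from myeloid progenitors. The libraries held 56353466 and 40364701 UMIs (Idh1-WT 1 and 2) and 47025425 and 53387528 UMIs (Idh1-R132H 1 and 2). After filtering, 4503, 3505, 3842 and 4430 cells were left, with median UMI counts of 8707, 7228, 8449 and 8573 and median gene counts of 2437, 2190, 2430 and 2392.5. The labels do not state whether the recipients of 1 group had separate donors, so p-values reach no further than these samples. EdgeR also pools variance over genes. Its median prior degrees of freedom were 86.1 in neutrophil precursor-, 216.9 in erythroid progenitor- and 3312.6 in neutrophil-like cells, and infinite in monocyte-like cells. Very small p-values there rest on the pooled variance and hardly on a gene's own spread between libraries. All differences below are Idh1-R132H minus Idh1-WT. Genes were tested with edgeR's quasi-likelihood test on counts summed per library and class, with Benjamini-Hochberg adjustment, and errors of mean CPM are SD over n = 2 libraries. Coordinates are from GRCm38/mm10 with GENCODE vM21.

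The marrow resolved into 30 clusters, of which 24 received a class name. The markers were fixed before the data were examined, but some limits of the naming rule were set after the clusters were seen. The classes ran from stem and multipotent progenitor-like cells through granulocyte-monocyte progenitor-like cells and neutrophil precursor-like cells to neutrophil-like cells. Monocyte-, dendritic cell-, erythroid-, megakaryocyte-, basophil-, lymphoid-primed, B- and T or NK-like cells were also present. A cluster led by Irf8, F13a1 and Ly6c2 held as many monocyte as granulocyte-monocyte progenitor markers and is described by those genes. Neutrophil-like cells made up 7.81% ± 0.0230 of the Idh1-WT libraries and 6.36% ± 0.144 of the Idh1-R132H libraries. Granulocyte-monocyte progenitor-like cells made up 47.6% ± 0.373 of the cells of the 3 neutrophil stages in Idh1-WT and 54.2% ± 2.21 in Idh1-R132H. Neutrophil-like cells made up 24.6% ± 0.0652 and 20.2% ± 1.33 of these stages, a log2 difference of −0.29 (SE 0.10). Neutrophil precursor-like cells, with 27.8% ± 0.308 and 25.5% ± 3.54, differed by less than the spread between replicates. Monocyte-like cells held 15.5% ± 1.44 and 20.7% ± 0.527 of the mature classes. No share passed edgeR's quasi-likelihood test after adjustment in any of the 4 families of shares. The smallest adjusted p among the stages was 0.0698, for both the granulocyte-monocyte progenitor-like (unadjusted p = 0.0465) and the neutrophil-like share (unadjusted p = 0.0276), and 1 of 15 shares of all cells had an unadjusted p below 0.05. The exact permutation p was 0.333 for both stages, the smallest that 2 libraries against 2 can give. The sort pooled equal cell numbers of 3 populations, which can set the shares of all cells and of the neutrophil stages. The mature classes were taken to lie within the total CD45.1-positive sort, which was not checked. Without Idh1-R132H 1 or Idh1-R132H 2, 2 or 3 of the stage shares passed, and without Idh1-R132H 1 the direction of the precursor share turned (log2 difference 0.01). Without Idh1-WT 2 the share of cells in unnamed clusters passed. Among Xist-carrying cells the neutrophil-like stage share was higher in Idh1-R132H (log2 difference 0.38). Such cells made up 9.40% and 8.03% of neutrophil-like cells in Idh1-WT and 9.27% and 10.5% in Idh1-R132H. Of granulocyte-monocyte progenitor-like cells they made up 77.4% and 59.4% in Idh1-WT but 51.8% and 38.3% in Idh1-R132H. Selecting by Xist can raise the neutrophil-like share by itself, so this value does not show a reversal.

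**Figure D1:**
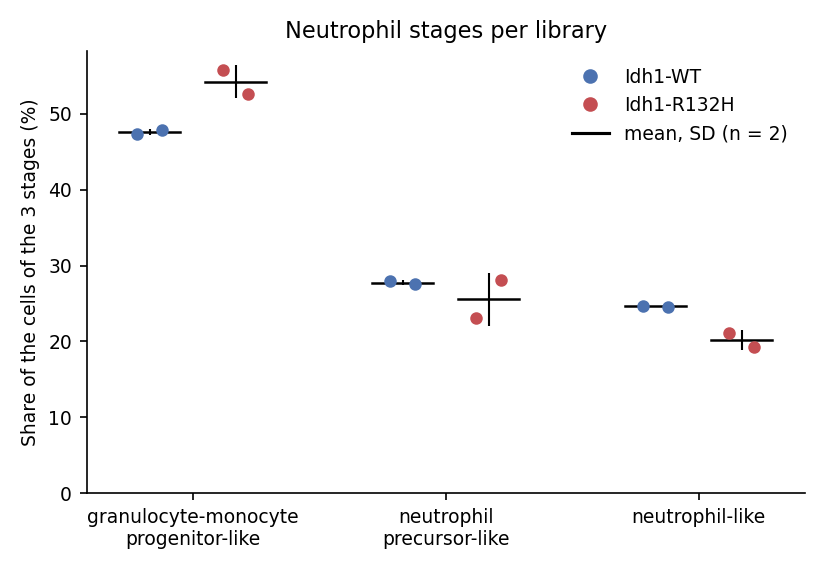
Share in percent of the cells of the 3 neutrophil stages held by each stage, as points per library for Idh1-WT and Idh1-R132H with the mean and SD of n = 2 libraries. The neutrophil-like share lay between 24.6% and 24.7% in Idh1-WT and between 19.3% and 21.2% in Idh1-R132H.

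Idh1 (chromosome 1, 65158616 to 65186500) was detected in every library. Its level in all cells summed was 59.3 and 62.9 CPM in Idh1-WT and 58.1 and 52.99 in Idh1-R132H. The 3′ counts do not read the mutated base, so these values describe expression and do not check the genotype labels. Idh1 was 236.7 ± 26.8 and 237.8 ± 4.03 CPM in monocyte-like cells, 75.5 ± 3.06 and 67.5 ± 4.22 in granulocyte-monocyte progenitor-like cells and 41.9 ± 3.20 and 30.6 ± 7.26 in neutrophil precursor-like cells. It did not pass in any class tested (edgeR adjusted p = 0.407 in granulocyte-monocyte progenitor-like and 0.603 in neutrophil precursor-like cells). The smallest p was in the progenitor cluster led by Irf8 and F13a1, with 115.8 ± 1.10 and 96.9 ± 4.78 CPM (log2 difference −0.26, unadjusted p = 0.000897, adjusted p = 0.115). The granulocytic transcription factors Cebpa, Cebpe, Spi1 and Gfi1, the primary granule genes Mpo and Elane, the secondary granule gene Ltf, the G-CSF receptor gene Csf3r and the mitochondrial isocitrate dehydrogenase gene Idh2 did not pass in the stem and multipotent progenitor-like class or in any neutrophil stage in which they were tested. In granulocyte-monocyte progenitor-like cells, Cebpa was 83.3 ± 3.36 and 88.3 ± 2.04 CPM, Cebpe 194.1 ± 36.02 and 161.5 ± 22.9, and Gfi1 39.8 ± 1.43 and 40.4 ± 4.38. Mpo was 9750 ± 361 and 9338 ± 152 in the same cells (log2 difference −0.06, SE 0.03). In neutrophil precursor-like cells, Ltf was 8250 ± 64.8 and 8178 ± 34.2 CPM. The fixed lists of secondary granule and neutrophil maturation genes were not called in granulocyte-monocyte progenitor-, neutrophil precursor- or neutrophil-like cells (camera, limma). None of the 14, 14 and 12 secondary granule genes tested there passed, and of 16, 16 and 17 maturation genes 1 fell in each class, Slpi.

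**Figure D2:**
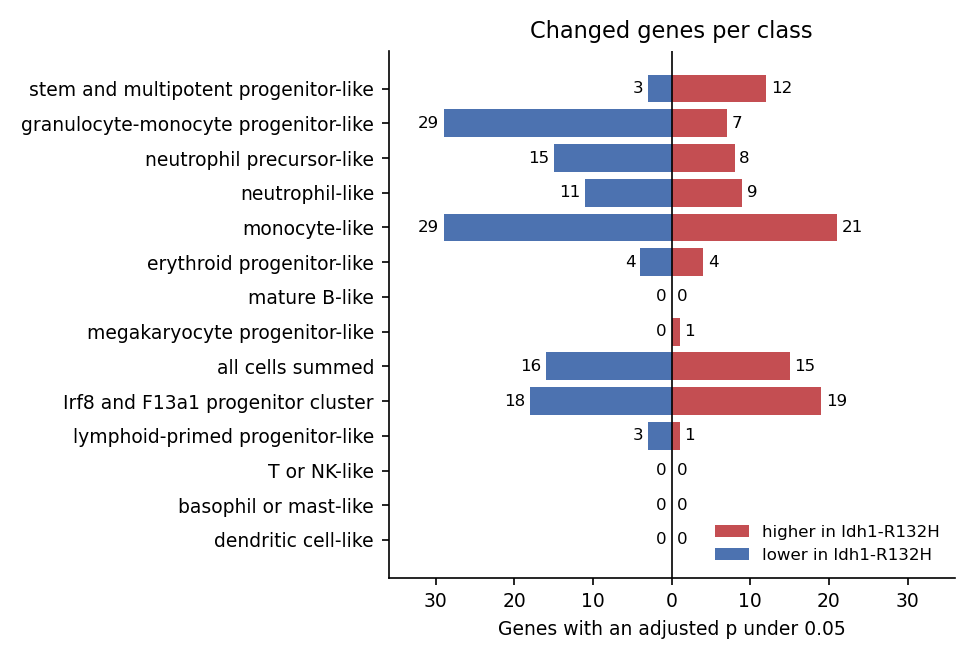
Number of genes with an edgeR adjusted p under 0.05 per class, with genes higher in Idh1-R132H to the right and genes lower to the left. Counts ran from 0 in mature B-, T or NK-, basophil or mast- and dendritic cell-like cells to 50 in monocyte-like cells.

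Stem and multipotent progenitor-like cells of Idh1-R132H marrow carried more transcript of the leukocyte surface genes Cd48 and Cd53, of the interferon-response genes Irf7 and Ifi27l2a and of the Rosa26 locus. Cd48, a SLAM-family receptor used to part stem cells from multipotent progenitors, rose from 80.9 ± 6.29 to 119.3 ± 5.38 CPM (log2 change 0.56, SE 0.08, adjusted p = 0.0110). The class was not divided into stem cells and multipotent progenitors. A different mix of these within the class was therefore not tested and cannot be told from a change per cell. The tetraspanin gene Cd53 rose from 52.8 ± 3.95 to 81.8 ± 6.45 (log2 change 0.63). Ms4a6c (0.56), the T-cell signalling adaptor gene Tespa1 (0.64), Wfdc17 (0.53) and the serine protease inhibitor gene Serpina3g (0.40) also rose. Gt(ROSA)26Sor, the non-coding transcript of the Rosa26 locus into which reporter alleles are often placed (chromosome 6, 113067428 to 113077333), rose from 5.49 ± 0.327 to 22.0 ± 1.45 CPM (log2 change 1.99, SE 0.14, adjusted p = 8.5e-06). Of 18 measured interferon-response genes, 2 rose and 16 did not pass, with 7 rising when adjusted over the list alone. Irf7, a transcription factor of this response, rose by a log2 change of 0.65 and the interferon-induced Ifi27l2a by 0.76. The list lay above the other genes (15 of 18 members higher, median 0.27, camera adjusted p = 3.6e-09; adjusted p = 0.571 with an estimated correlation). The metallothionein gene Mt1 fell from 56.7 ± 5.20 to 33.7 ± 4.795 (log2 change −0.75), as did Sdpr, which encodes a caveolar coat protein (−1.14), and the chemokine gene Ccl5 (−0.68). Of the Ccl5 UMIs of Idh1-WT, 5 cells held 75.6%, and in Xist-carrying cells its direction turned (0.068). None of the 14 erythroid genes or the 13 immediate early genes passed alone. Their lists lay lower (medians −0.33 and −0.28, camera adjusted p = 0.0015 and 1.2e-05; adjusted p = 0.571 and 0.639 with an estimated correlation). Of 12 myeloid cytokine receptor genes 1 rose, of 10 monocyte and macrophage genes 1 rose, and none of 10 primary granule genes passed. These 3 lists lay higher, with medians of 0.20, 0.20 and 0.09 (camera adjusted p = 0.0028, 0.0051 and 0.0051; adjusted p = 0.571, 0.571 and 0.655 with an estimated correlation). In all, 15 of 11874 tested genes changed, 12 up and 3 down, 664 had an unadjusted p below 0.05 (593.7 expected by chance), and DESeq2 called 11. With each cell classed by its markers, or clustered again at a minimum of 300 UMIs, the count was 5. Ptpru had 3 counts in Idh1-WT and 73 in Idh1-R132H (ratio 23.5, 95% interval 7.74 to 116.7), and Syce1 had 0 and 40 (at least 12.9-fold higher, with a floor of 3 counts over the group). With Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2 left out in turn the count was 296, 167, 70 or 31, and 15, 15, 15 or 12 of the 15 genes still passed. Irf7, Wfdc17 and Serpina3g did not pass without Idh1-R132H 2. Without Idh1-WT 2 the immediate early list turned its direction and lost its call (adjusted p = 0.900).

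Granulocyte-monocyte progenitor-like cells of Idh1-R132H marrow had more genes with lower than with higher transcript levels. Dmkn, which encodes the secreted protein dermokine (chromosome 7, 30763756 to 30781063), fell from 105.8 ± 3.05 to 57.0 ± 2.36 CPM (log2 change −0.89, SE 0.06, adjusted p = 2.2e-09). Dusp1, the gene of a phosphatase that switches off MAP kinases, fell from 41.0 ± 1.05 to 25.7 ± 1.26 (log2 change −0.67, SE 0.09, adjusted p = 0.00011). Glutathione reductase (Gsr, −0.28) and the glutathione S-transferase genes Gstm1 (−0.25) and Mgst2 (−0.34) fell, as did the receptor gene Trem3, from 195.8 ± 13.9 to 145.2 ± 0.899 (−0.43). Slpi, which encodes an inhibitor of neutrophil elastase and cathepsin G (chromosome 2, 164354070 to 164389095), fell from 245.5 ± 5.42 to 203.6 ± 16.1 (−0.27, adjusted p = 0.0141). The C-type lectin genes Mgl2 (−0.62) and Clec12a (−0.20) and the adhesion gene Vcam1 (−0.59) fell. Of 15 cholesterol synthesis genes, all 15 were lower and 1, Fdps for farnesyl diphosphate synthase, fell (from 150.9 ± 6.74 to 119.5 ± 2.53), with 2 falling when adjusted over the list alone. The list median was −0.30 (camera adjusted p = 7.9e-08; adjusted p = 0.553 with an estimated correlation). Of 13 immediate early genes 2 fell, Dusp1 and Junb (−0.36), 12 were lower, and 8 fell when adjusted over the list alone (camera adjusted p = 3.6e-09; adjusted p = 0.553 with an estimated correlation). Of 18 G2 and M phase genes 1 fell, Ube2c (−0.27), 16 were lower, and 8 fell when adjusted over the list alone (camera adjusted p = 6.2e-10; adjusted p = 0.553 with an estimated correlation). Ribonucleotide reductase (Rrm2, −0.26), cytochrome c (Cycs, −0.21) and enolase (Eno1, −0.17) also fell. Of 85 ribosomal protein genes 2 rose, Rps12 (0.17) and Rplp1 (0.19), 81 were higher, and 43 rose when adjusted over the list alone (median 0.08, camera adjusted p = 3.6e-27; adjusted p = 0.553 with an estimated correlation). None of 10 primary granule genes passed. Their list lay lower (8 of 10 lower, median −0.07, camera adjusted p = 0.0041; adjusted p = 0.563 with an estimated correlation). Gdf3, of the TGF-beta family, rose from 16.9 ± 0.171 to 30.0 ± 3.20 (log2 change 0.82), and Gt(ROSA)26Sor rose by a log2 change of 1.03. In all, 36 of 11036 genes changed, 7 up and 29 down, 1105 had an unadjusted p below 0.05 (551.8 expected by chance), and DESeq2 called 21. Srp54b (−0.41) and Pnp2 (−0.92) share reads with near-identical copies and are uncertain. The Y-linked Kdm5d rose with the group (log2 change 1.68), and in Xist-carrying cells alone the count was 23. Leaving out Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2, the count was 93, 62, 142 or 54, and 24, 29, 26 or 19 of the 36 genes still passed. Dmkn, Dtwd1, Dusp1, Fdps, Gdf3, Gsr, Gstm1, Gt(ROSA)26Sor, Mtus2, Srp54b and Trem3 passed in all 4 of these fits, and Slpi did not without Idh1-R132H 1.

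The progenitor cluster led by Irf8, F13a1 and Ly6c2 showed higher Ly6c2, Irf5 and Ifitm3 and lower Slpi and Dmkn in Idh1-R132H. Ly6c2, a surface antigen of inflammatory monocytes, rose from 2658 ± 31.3 to 3388 ± 187 CPM (log2 change 0.35, adjusted p = 2.0e-05). Irf5, a transcription factor of inflammatory cytokine genes, rose from 12.8 ± 1.00 to 23.9 ± 2.32 (0.91). The lectin receptor gene Clec4a2 (0.68), complement C3 (0.74), the NADPH oxidase gene Cybb (0.53), S100a4 (0.72), Slfn2 (0.63) and Lst1 (0.32) rose. Ifitm3, which restricts viral entry and belongs to a family with shared sequence, rose from 284.0 ± 14.0 to 417.7 ± 38.9 (0.55). Of 14 interferon-response genes 1 rose and 13 were higher, with 2 rising when adjusted over the list alone (median 0.54, camera adjusted p = 1.9e-06; adjusted p = 0.382 with an estimated correlation). Of 12 monocyte and macrophage genes 2 rose (Ly6c2 and Psap, 0.22) and 1 fell, Ly86 (−0.41), a partner of a toll-like receptor relative. Slpi fell from 772.4 ± 6.15 to 578.3 ± 45.7 (−0.42) and Dmkn from 111.8 ± 0.222 to 54.7 ± 1.54 (−1.03, adjusted p = 1.2e-09). The bicarbonate transporter gene Slc4a8 (−1.11), the branched-chain aminotransferase gene Bcat1 (−1.51), Abhd11 (−0.45) and Fdps (−0.31) also fell. Of 14 cholesterol synthesis genes 1 fell and 13 were lower (median −0.28, camera adjusted p = 1.5e-05; adjusted p = 0.382 with an estimated correlation). This cluster was tested only after the data were seen. Of 10203 genes 37 changed, 19 up and 18 down, 984 had an unadjusted p below 0.05 (510.15 expected by chance), and DESeq2 called 12. In Xist-carrying cells alone the count was 14. Without Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2 the count was 200, 72, 54 or 24, and 32, 27, 25 or 15 of the 37 genes still passed. Slpi, Dmkn, Irf5, Clec4a2, C3, Ifitm3, Ly86, Slc4a8, Abhd11, Gtf2f2, Gdf3 and Gt(ROSA)26Sor passed in all 4 of these fits.

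Neutrophil precursor-like cells, the stage that makes secondary granules, had lower Slpi and higher levels of 5 of 12 mitochondrially encoded genes in Idh1-R132H. Slpi fell from 734.7 ± 34.2 to 471.9 ± 56.1 CPM (log2 change −0.65, SE 0.09, adjusted p = 1.9e-07). Stfa1, of the stefin A inhibitors of cysteine proteases (chromosome 16, 36276951 to 36285373), fell from 45.3 ± 6.34 to 6.07 ± 3.14 (−3.03, SE 0.28, adjusted p = 2.9e-14), and its neighbour BC100530 fell by 3.21. Stfa3 had 33 counts in Idh1-WT and 3 in Idh1-R132H (ratio 0.0914, 95% interval 0.0179 to 0.291). The genes of this stefin cluster share reads with near-identical copies, so the assignment to single members is uncertain. Few cells carried them: in Idh1-WT, 5 cells held 69.8% of the Stfa1, 92.5% of the BC100530 and 66.7% of the Stfa3 UMIs. The adenine salvage gene Aprt fell from 365.5 ± 17.1 to 241.2 ± 20.9 (−0.59), the actin-binding Tmsb10 from 565.4 ± 32.1 to 388.1 ± 14.9 (−0.54) and the phospholipase gene Gdpd3 from 66.7 ± 4.99 to 33.1 ± 3.72 (−1.04). Cdk2ap2 (−0.45), Efhd2 (−0.55) and the Fc receptor gene Fcgr4 (−0.96) fell as well. Of 12 mitochondrially encoded genes, 5 rose: mt-Nd1 (0.55), mt-Nd2 (0.63) and mt-Nd3 (0.88) of respiratory complex I, mt-Cytb (0.39) and mt-Co2 (0.33). When adjusted over the list alone 9 rose (median 0.31, camera adjusted p = 5.4e-18; adjusted p = 0.790 with an estimated correlation). With cells above 5% mitochondrial UMIs left out, none of the 5 passed and the list median was 0.08. Such cells numbered 2 and 0 in Idh1-WT and 8 and 8 in Idh1-R132H and held 2.55%, 0%, 19.5% and 12.7% of the mitochondrial UMIs of the class. None of 10 cholesterol synthesis genes passed, and all 10 were lower (median −0.33, camera adjusted p = 0.0033; adjusted p = 0.812 with an estimated correlation). Ifi27l2a rose by a log2 change of 0.64. Xist fell from 215.7 ± 32.2 to 130.6 ± 7.47 (−0.74), and the X-linked Xlr had 9 counts in Idh1-WT and 70 in Idh1-R132H. In all, 23 of 6903 genes changed, 8 up and 15 down, 406 had an unadjusted p below 0.05 (345.15 expected by chance), and DESeq2 called 6. In Xist-carrying cells alone edgeR called 0. With Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2 left out in turn the count was 27, 16, 34 or 27, and 14, 11, 20 or 16 of the 23 genes still passed. Slpi, Stfa1, BC100530, Aprt, Gdpd3, mt-Nd1, Xist and Xlr passed in all 4 of these fits.

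Neutrophil-like cells repeated the lower Slpi and had higher levels of 6 of 10 mitochondrially encoded genes in Idh1-R132H. Slpi fell from 4492 ± 14.1 to 2637 ± 37.5 CPM (log2 change −0.77, SE 0.09, adjusted p = 2.1e-15). Stfa1 fell from 313.0 ± 111 to 87.8 ± 3.38 (−1.81, SE 0.20) and Stfa3 by 3.14 on the log2 scale, with the same uncertainty over shared reads and with 54.5% and 69.2% of the Idh1-WT UMIs in 5 cells. Ltb, the gene of the cytokine lymphotoxin beta, fell from 403.8 ± 55.3 to 252.9 ± 17.5 (−0.66), the surface antigen gene Cd52 fell from 6358 ± 192 to 5140 ± 40.3 (−0.31), and Tmsb10 (−0.58) and Cdk2ap2 (−0.47) fell. Of 10 mitochondrially encoded genes 6 rose and all 10 were higher (median 0.65, camera adjusted p = 1.1e-23; adjusted p = 0.652 with an estimated correlation). The complex V subunit gene mt-Atp6 rose from 971 ± 86.1 to 1676 ± 170 CPM (0.79, adjusted p = 1.8e-11), the complex IV subunit gene mt-Co3 from 1102 ± 97.0 to 1851 ± 128 (0.75), and mt-Nd1 by a log2 change of 0.91. These transcripts made up 0.449% and 0.489% of the UMIs of the class in Idh1-WT and 0.755% and 0.731% in Idh1-R132H. Counts expected from free RNA came to 1.99, 0.900, 0.802 and 0.969 of those observed in Idh1-WT 1 and 2 and Idh1-R132H 1 and 2. The immediate early gene Fos (0.49), the kinase gene Pim1 (0.72) and the chemokine gene Cxcl2 rose, the last from 8 to 33 counts, of which 5 cells held 54.5%. Of 9 immediate early genes 1 rose, Fos, and 3 rose when adjusted over the list alone (camera adjusted p = 0.0062; adjusted p = 0.827 with an estimated correlation). This list turned its direction in Xist-carrying cells (camera adjusted p = 0.595). The neutrophil maturation list had a median of −0.02 and was not called. In all, 20 of 3015 genes changed, 9 up and 11 down, 236 had an unadjusted p below 0.05 (150.75 expected by chance), and DESeq2 called 4. With each cell classed by its markers 0 genes were called, and with free RNA subtracted 7. In Xist-carrying cells alone 6 genes were called, and Stfa1 (1.05) and Fos (−0.85) turned their direction there. Those were only 33 and 22 cells in Idh1-WT and 23 and 29 in Idh1-R132H. Leaving out Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2, the count was 19, 11, 14 or 10, and 12, 9, 11 or 9 of the 20 genes still passed. Slpi, Stfa1, mt-Atp6, mt-Co2, mt-Co3 and mt-Nd1 passed in all 4 of these fits.

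Monocyte-like cells had lower Slpi and higher Ifi27l2a, Irf7, Rsad2 and Ifitm3 in Idh1-R132H. The 3 genes of C1q, the first component of the classical complement pathway that macrophages make, lay together on chromosome 4. C1qa had 89 counts in Idh1-WT and 1 in Idh1-R132H (ratio 0.00905, 95% interval 0.000227 to 0.0517), C1qc had 71 and 3 (ratio 0.0340, 0.00685 to 0.104), and C1qb fell from 48.4 ± 8.20 to 4.47 ± 0.259 CPM (log2 change −3.40). In Idh1-WT these UMIs came from 7, 8 and 11 cells, of which 5 held 96.6%, 93.0% and 90.4%, so the falls rest on a few cells. In all cells summed C1qa had 129 counts in Idh1-WT and 37 in Idh1-R132H and C1qb had 148 and 40, so most C1q counts of Idh1-R132H lay outside this class. Cd209a, a lectin gene of monocyte-derived dendritic cells, fell from 83.8 ± 8.43 to 28.2 ± 5.04 (−1.59, SE 0.21, adjusted p = 8.2e-11), with 56.7% of its Idh1-WT UMIs in 5 cells. None of 6 MHC class II genes passed. Their list lay lower (median −0.49, camera adjusted p = 5.7e-05; adjusted p = 0.754 with an estimated correlation), and it turned its direction in Xist-carrying cells (median 0.20, adjusted p = 0.139). Slpi fell from 493.6 ± 35.4 to 236.1 ± 6.46 (−1.06, SE 0.09, adjusted p = 6.2e-29), and Dmkn (−2.09, 57.1% of its Idh1-WT UMIs in 5 cells), Trem3 (−1.09), the histone-citrullinating enzyme gene Padi4 (−0.99) and the cytokine gene Mif (−0.55) also fell. Ifi27l2a rose from 1494 ± 95.04 to 2883 ± 307 (0.95, SE 0.05, adjusted p = 6.3e-68). Of 17 interferon-response genes 4 rose, Ifi27l2a, Irf7 (0.58), Rsad2 (from 12 to 55 counts, 52.7% of the latter in 5 cells) and Ifitm3 (0.24), and all 17 were higher, with 9 rising when adjusted over the list alone. The list median was 0.49 (camera adjusted p = 1.2e-14; adjusted p = 0.754 with an estimated correlation). The antigen-presentation genes B2m (0.25) and H2-D1 (0.19) and the monocyte genes Ly6c2 (0.20), Ms4a6c (0.29), Plac8 (0.25) and S100a4 (0.33) rose. Of 12 mitochondrially encoded genes 2 fell, mt-Nd3 (−0.59) and mt-Nd1 (−0.23), and the list lay lower (median −0.11, camera adjusted p = 0.0015; adjusted p = 0.754 with an estimated correlation). With cells above 5% mitochondrial UMIs left out, neither passed and the list median was −0.034. With a minimum of 300 UMIs mt-Nd3 turned its direction (0.026). Xist fell (−0.62) and the Y-linked Eif2s3y rose (1.93) with the group. In all, 50 of 6970 genes changed, 21 up and 29 down, 525 had an unadjusted p below 0.05 (348.5 expected by chance), and DESeq2 called 8. In Xist-carrying cells alone the count was 33, with equal cell numbers 32, and with each cell classed by its markers 7. Ifi27l2a lost its call in 5 of 20 alternatives (log2 change 0.84 to 1.18 over all), while Slpi kept it in 20 of 20. Without Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2 the count was 20, 21, 56 or 43, and 15, 17, 34 or 23 of the 50 genes still passed. C1qa, C1qb, C1qc, Cd209a, Slpi, Ifi27l2a, B2m, Xist and Xlr passed in all 4 of these fits.

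**Figure D3:**
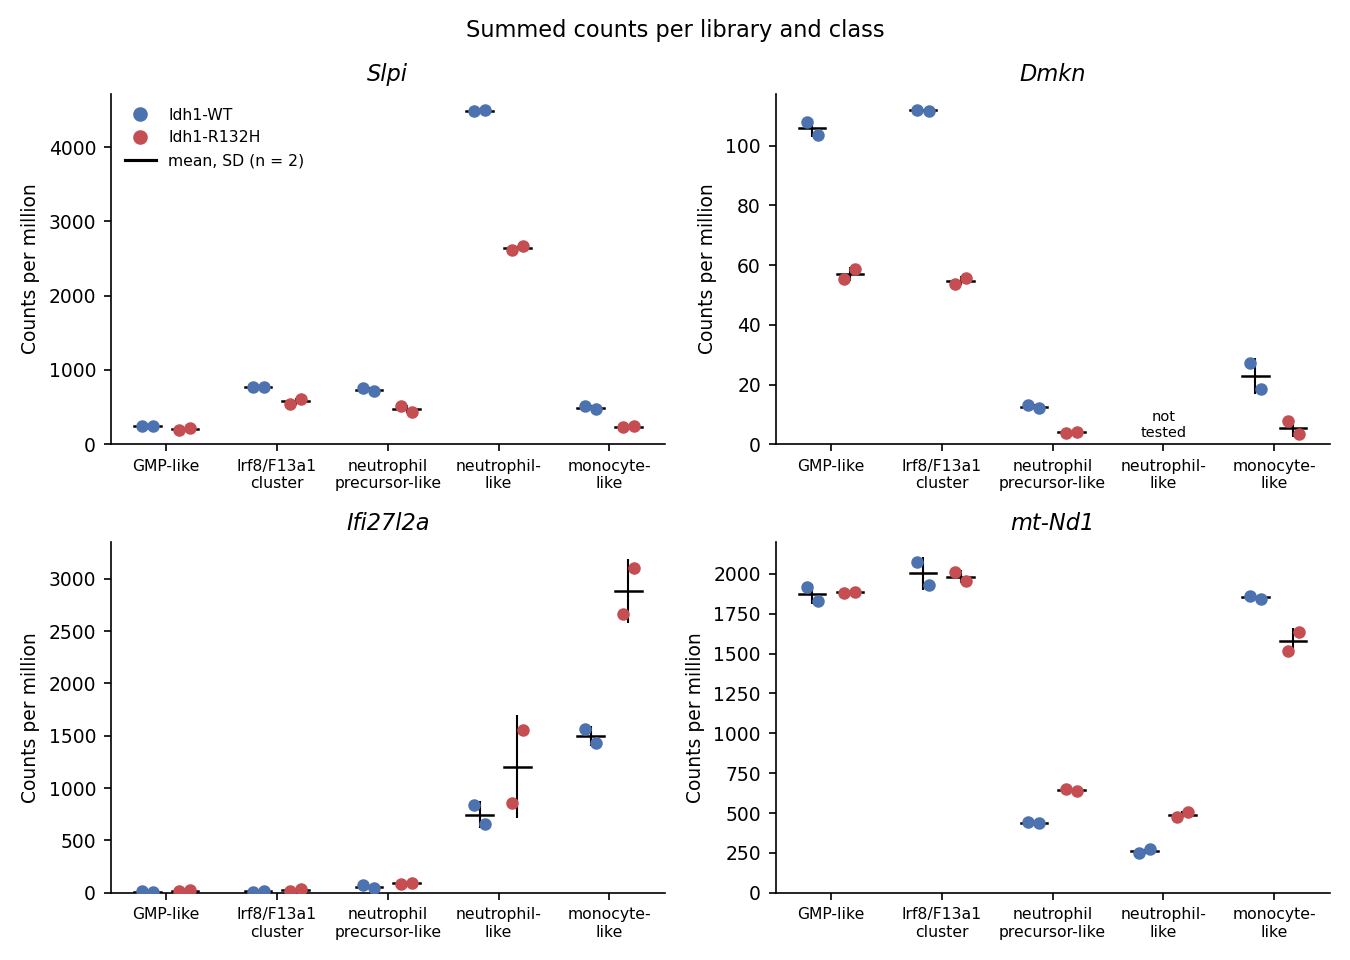
CPM of Slpi, Dmkn, Ifi27l2a and mt-Nd1 in 5 myeloid classes, as points per library with the mean and SD of n = 2 libraries for Idh1-WT and Idh1-R132H. In neutrophil-like cells the Slpi points of Idh1-R132H lay at 2611 and 2664, below those of Idh1-WT at 4482 and 4502.

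Erythroid progenitor-like cells had lower Ccnd1, Kpna2, Ube2c and Gm10076 in Idh1-R132H. The cyclin D1 gene Ccnd1 fell from 14.1 ± 2.26 to 3.38 ± 1.04 CPM (log2 change −1.97), the nuclear import gene Kpna2 from 135.9 ± 11.3 to 82.2 ± 0.131 (−0.72) and the ubiquitin-conjugating enzyme gene Ube2c from 234.4 ± 15.1 to 168.0 ± 10.6 (−0.49). Gt(ROSA)26Sor (2.70), Xlr (2.95), Golga3 (0.95) and 1700097N02Rik (0.72) rose. Of the Golga3 UMIs of Idh1-R132H 5 cells held 73.5%, and its direction turned in Xist-carrying cells (−0.59). Of 18 G2 and M phase genes 1 fell and 15 were lower (median −0.26), and of 18 erythroid genes none passed and 14 were lower (median −0.23). Both lists were called (camera adjusted p = 1.4e-06 for each; adjusted p = 0.697 for each with an estimated correlation). The secondary granule list lay higher in these cells (median 0.82, camera adjusted p = 3.2e-06; adjusted p = 0.697 with an estimated correlation) with Ltf at 24.3 ± 0.183 and 56.7 ± 46.5, and without Idh1-R132H 2 it turned its direction (adjusted p = 0.174). In all, 8 of 7970 genes changed, 404 had an unadjusted p below 0.05 (398.5 expected by chance), and DESeq2 called 0. With Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2 left out in turn the count was 18, 68, 29 or 7, and Gt(ROSA)26Sor and Xlr passed in all 4 of these fits.

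In megakaryocyte progenitor-like cells the only gene edgeR called among 6919 was Xlr, with 0 counts in Idh1-WT and 32 in Idh1-R132H, at least 12.4-fold higher with a floor of 3 counts over the group. There, 462 genes had an unadjusted p below 0.05 (345.95 expected by chance) and DESeq2 called 0. None of 18 G2 and M phase genes passed, 17 were higher and 9 rose when adjusted over the list alone (median 0.45, camera adjusted p = 3.3e-12; adjusted p = 0.554 with an estimated correlation). None of 14 megakaryocyte genes passed and 13 were higher (median 0.24, camera adjusted p = 0.0005; adjusted p = 0.554 with an estimated correlation). In Xist-carrying cells this list turned its direction (camera adjusted p = 0.529) and 0 genes were called. Leaving out Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2, the count was 13, 7, 45 or 7, and Xlr did not pass without Idh1-R132H 2. In lymphoid-primed progenitor-like cells 4 genes changed, and 375.65 genes were expected by chance at an unadjusted p below 0.05. Xist (−0.78), the nucleoside diphosphate kinase gene Nme2 (−0.56) and the haemoglobin gene Hbb-bt (−1.89, 57.3% of its Idh1-WT UMIs in 5 cells) fell, and Ifitm1, of a family with shared sequence, rose (0.59). In that class 399 genes had an unadjusted p below 0.05, DESeq2 called 1, and without Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2 the count was 8, 7, 28 or 10. Hbb-bt did not pass without Idh1-WT 1 and Nme2 did not without Idh1-R132H 2. Of the 12 interferon-response genes measured there, none passed and 11 were higher (median 0.32, camera adjusted p = 0.00016; adjusted p = 0.961 with an estimated correlation). In mature B-like cells edgeR called 0 of 3508 genes, with 219 at an unadjusted p below 0.05 (175.4 expected by chance) and 0 by DESeq2. All 7 MHC class II genes were lower there and none passed, with 3 falling when adjusted over the list alone (median −0.33, camera adjusted p = 0.00011; adjusted p = 0.784 with an estimated correlation). Without Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2, 35, 8, 17 or 2 genes were called in mature B-like cells. EdgeR called 0 genes in T or NK-, basophil or mast- and dendritic cell-like cells, with 94, 347 and 206 at an unadjusted p below 0.05 (108.95, 297.1 and 130.55 expected by chance) and 0 by DESeq2 in each. With 1 library left out the counts there ran from 5 to 34, 4 to 17 and 4 to 25. B precursor-like cells, with 17 to 34 cells per library, were too few for a test.

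Summed over all cells, which mixes composition with expression, 31 of 13301 genes changed, 15 up and 16 down. Dmkn fell from 55.2 ± 3.13 to 29.2 ± 0.242 CPM (log2 change −0.92), Slpi from 329.9 ± 11.7 to 235.3 ± 11.04 (−0.49) and Dusp1 from 66.7 ± 4.88 to 49.6 ± 4.51 (−0.43). Gt(ROSA)26Sor (1.41), Gdf3 (0.80), Wfdc17 (0.56), Ly6c2 (0.25) and Cdk6, a kinase of the cell cycle's start (0.27), rose. Hoxc4 had 0 counts in Idh1-WT and 41 in Idh1-R132H, at least 13.1-fold higher. Of 19 interferon-response genes none passed and 18 were higher (median 0.26), and of 18 erythroid genes none passed and 17 were lower (median −0.38). Both lists were called (camera adjusted p = 2.2e-09 and 1.1e-10; adjusted p = 0.632 for each with an estimated correlation). At an unadjusted p below 0.05 there were 1038 genes (665.05 expected by chance), and DESeq2 called 33. Without Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2 the count was 86, 88, 17 or 19, and 20, 23, 8 or 9 of the 31 genes still passed. Dmkn, Slpi, Stfa1, Gdf3, Wfdc17 and Gt(ROSA)26Sor passed in all 4 of these fits. Among cells with UMIs of Xist or of Y-linked genes but not of both, the share with Xist was 92.7% and 73.3% in Idh1-WT and 67.6% and 55.1% in Idh1-R132H.

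Across the classes other than all cells summed, 137 genes were called in at least 1 class, 42 in at least 2 and 10 in at least 3. Slpi fell in 5 classes, Dmkn in 4, and Trem3, Tmsb10, Gm10076 and Xist in 3 each. Gt(ROSA)26Sor and the X-linked Xlr rose in 4 and Ifi27l2a in 3, and mt-Nd1 rose in 2 and fell in 1. Whether an effect differed between adjacent stages was tested with a genotype by class term, with the library as a block. Between stem and multipotent and granulocyte-monocyte progenitor-like cells, 2 of 12129 genes differed, with lower effects on Cd48 and Cd53 in the latter, where neither passed (adjusted p = 0.000505 and 0.0041). Between granulocyte-monocyte progenitor- and neutrophil precursor-like cells, 9 of 10555 genes differed. Slpi fell further in the precursors (log2 difference of effect −0.40, adjusted p = 0.033), while the effects on Junb (0.51) and Fos (0.80) were higher in the precursors. Between neutrophil precursor- and neutrophil-like cells, 3 of 6037 genes differed, and mt-Atp6 (0.50) and mt-Co3 (0.48) were raised more in the neutrophil-like cells. At an unadjusted p below 0.05 there were 712, 587 and 262 genes in these 3 tests. With Idh1-WT 1, Idh1-WT 2, Idh1-R132H 1 or Idh1-R132H 2 left out in turn the first count was 175, 16, 11 or 0, the second 4, 12, 19 or 4 and the third 1, 2, 0 or 0. Of all gene list calls, none held with the correlation estimated from the data. With 2 libraries per group that setting could hardly call any list, so the loss does not refute a shift. The preset correlation is an assumption, so the list calls stay unsettled.

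**Figure D4:**
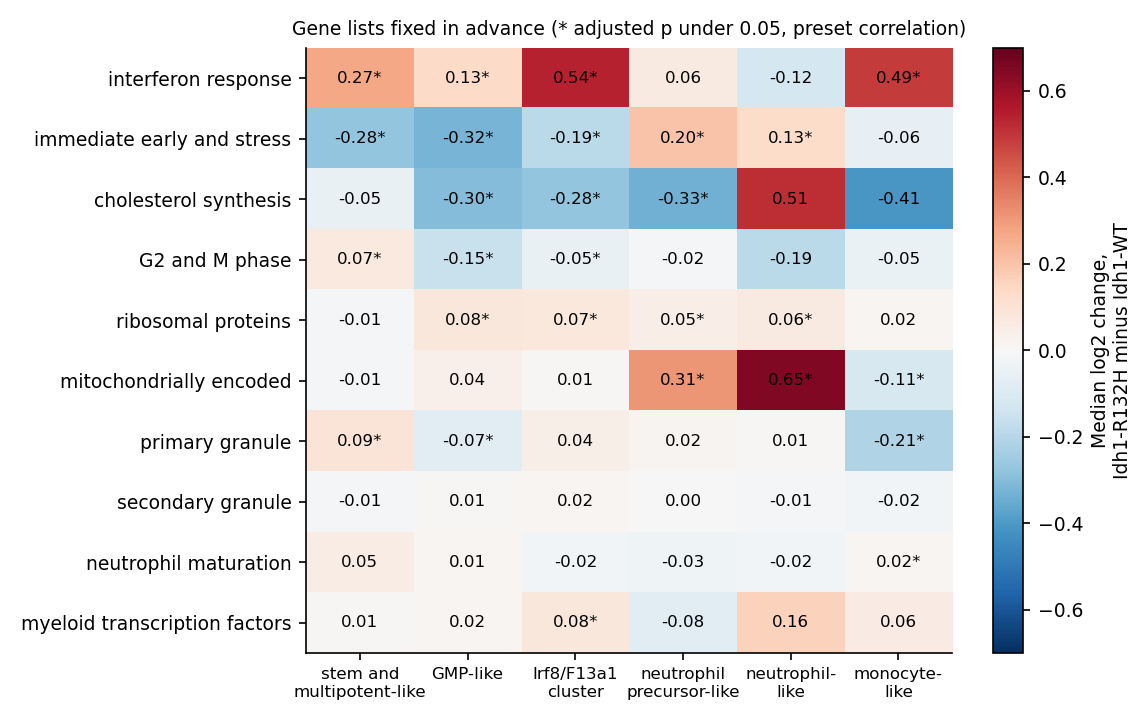
Median log2 change (Idh1-R132H minus Idh1-WT) of 10 of the gene lists in 6 classes, with an asterisk where camera's adjusted p with the preset correlation was under 0.05. The mitochondrially encoded list reached 0.65 in neutrophil-like cells, and the interferon list 0.54 in the Irf8 and F13a1 progenitor cluster.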

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

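The tests of explanations below were chosen only after the data were seen, those on Xist-carrying cells before and the others after the result they measure. Between adjacent classes the difference between groups was unequal for 14 gene and class pairs, by a test of the difference itself. From stem and multipotent to granulocyte-monocyte progenitor-like cells the log2 difference of effect was −0.59 for Cd48 and −0.55 for Cd53. From granulocyte-monocyte progenitor- to neutrophil precursor-like cells it was −0.40 for Slpi, −0.58 for Tmsb10, −0.56 for Aprt, −4.81 for Gm26737, 0.51 for Junb, 0.80 for Fos, 0.54 for mt-Nd1, 0.66 for mt-Nd2 and 0.85 for mt-Nd3. From neutrophil precursor- to neutrophil-like cells it was 1.255 for Xist, 0.50 for mt-Atp6 and 0.48 for mt-Co3. Xist follows the mix of male and female cells, so its value need not be an effect of the genotype. In neutrophil-like cells Xist had 58 counts in Idh1-WT and 72 in Idh1-R132H. Gm26737 had a mean log2 CPM of only 1.33, so its value is uncertain.

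Slpi fell in monocyte-like cells by a log2 change of −1.06. RNA from other cells is argued against, since the change was −1.07 after subtraction of free RNA estimated in mature B-like cells and −1.09 with the higher estimate from T or NK-like cells. A different mix of male and female cells is argued against as the whole cause, since the change was −1.24 in Xist-carrying cells. This selection does not tell donor from recipient cells. A lower Slpi transcript level in mutant monocytes may remain, and measuring Slpi in sorted monocytes of further mice would test it.

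Of the mitochondrially encoded genes, 5 of 12 rose in neutrophil precursor- and 6 of 10 in neutrophil-like cells of Idh1-R132H. The list was called in both classes with the preset correlation only. Without cells above 5% mitochondrial UMIs the list median was 0.54 in neutrophil-like cells, against cells above 5% as the whole cause there. Only 3 and 3 cells in Idh1-WT and 6 and 4 in Idh1-R132H were left out. The median neutrophil-like cell held 0.378% and 0.349% in Idh1-WT and 0.417% and 0.438% in Idh1-R132H. Damaged cells below 5% therefore stay open. In the precursors the list median was 0.084, and damaged cells stay open there too. Leaving cells out by this share lowers it by construction, and the median precursor-like cell also held more (0.556% and 0.517% in Idh1-WT, 0.621% and 0.607% in Idh1-R132H). In the precursors the median was 0.41 after subtraction of free RNA estimated in mature B-like cells, against that source. With the estimate from T or NK-like cells it was 0.93. That estimate was 573 UMIs per cell in Idh1-WT 1 against 243, 258 and 313 in Idh1-WT 2 and Idh1-R132H 1 and 2. It also removes most from Idh1-WT 1, so 0.93 does not settle this either. In Xist-carrying precursor-like cells the median was 0.22 (SE 0.12 over genes), which leaves the mix of male and female cells open. This SE comes from the spread over the 12 genes of the list, which share the same libraries. It does not measure the spread between libraries. In neutrophil-like cells free RNA stays open, with a smallest ratio of expected to observed UMIs of 0.802. Less mature cells stay open too, since the maturation list's median of −0.021 decides nothing.

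Gt(ROSA)26Sor rose in stem and multipotent progenitor-like cells. A different mix of male and female cells is argued against as the whole cause, since the log2 change was 1.99 in Xist-carrying cells. A donor variant of the surrounding segment could not be excluded: 2 of 135 changed genes and 152 of 12414 tested genes lay within 15 Mb (odds ratio 1.22, 95% interval 0.144 to 4.56, exact Fisher p = 0.682). The 2 were Gdf3 and Clec4a2, both higher in Idh1-R132H. Within 15 Mb of Idh1 lay 1 of 136 changed genes, Sdpr, and 130 of 12414 tested genes (odds ratio 0.698, 95% interval 0.0174 to 4.02). For Gdf3, Clec4a2 and Sdpr a variant near these loci cannot be told from an effect of the mutation. A different number or state of reporter copies at Rosa26 may also explain the rise of Gt(ROSA)26Sor and was not tested. Genotyping Rosa26 would test it.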

How the results depend on the processing

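Alternatives on Xist-carrying cells, top-scoring doublets and low-UMI clusters were chosen after seeing the data; where a value moved, the cause was not tested. Over all alternatives 3014 gene values kept direction and call, 1188 lost the call and 10 reversed; for gene lists the numbers were 411, 222 and 17. Counts (of changed genes, passing shares, called lists and genes differing between adjacent classes) moved beyond 1.5 times in 138 cases and not in 220; moved counts of the lymphoid-primed, T or NK-, basophil or mast- and dendritic cell-like classes are in these totals and not listed below. With a minimum of 300 UMIs the counts were 5 (stem and multipotent), 12 (monocyte), 3 (megakaryocyte) and 18 (all cells), and Prtn3 (0.064) and mt-Nd3 (0.026) reversed in monocyte-like cells. With 1000 UMIs they were 10 (neutrophil) and 4 (mature B), with at most 5% mitochondrial UMIs 15 (neutrophil precursor) and 8 (mature B), and with doublet calls kept 4 (mature B). At the higher resolution they were 14 (monocyte), 5 (erythroid) and 6 (megakaryocyte), Prtn3 reversed (0.080), and 1 share among progenitor classes passed. With a class per cell they were 5 (stem and multipotent), 11 (neutrophil precursor), 0 (neutrophil), 7 (monocyte), 3 (mature B) and 22 (megakaryocyte), and Prtn3 (0.083), Tmem245 (0.14) in monocyte-like cells and the granulocyte-monocyte progenitor-like share (−0.042) reversed. With equal cell numbers they were 16 (granulocyte-monocyte progenitor), 32 (monocyte), 13 (erythroid), 27 (megakaryocyte) and 20 (Irf8 and F13a1 cluster). Library totals gave 3 (megakaryocyte), and subtraction of free RNA 7 (neutrophil) and 17 (all cells). DESeq2 gave 21 (granulocyte-monocyte progenitor), 6 (neutrophil precursor), 4 (neutrophil), 8 (monocyte), 0 (erythroid), 0 (megakaryocyte) and 12 (Irf8 and F13a1 cluster). Without a filter the counts were 94 (stem and multipotent), 127 (granulocyte-monocyte progenitor), 15 (erythroid), 17 (mature B), 24 (megakaryocyte), 226 (all cells) and 95 (Irf8 and F13a1 cluster). The replicate block gave 14 (erythroid), 26 (mature B), 10 (megakaryocyte) and 85 (all cells). The labels do not pair the mice, and the correlation of the deviations of same-numbered libraries from their group means was −0.28 in granulocyte-monocyte progenitor-like cells. Removal of top-scoring doublets gave 17 (erythroid). TMM factors let 1 stage share pass. With an estimated correlation 0 gene lists were called, a setting that could hardly call any with 2 libraries per group.

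In Xist-carrying cells the counts were 23 (granulocyte-monocyte progenitor), 0 (neutrophil precursor), 6 (neutrophil), 33 (monocyte), 4 (erythroid), 0 (megakaryocyte), 14 (Irf8 and F13a1 cluster), 42 gene lists, and 1, 1 and 1 genes in the 3 tests between adjacent classes. Log2 changes reversed there for Ccl5 in stem and multipotent (0.068), Fos (−0.85) and Stfa1 (1.05) in neutrophil-, Xist in monocyte- (0.015) and Golga3 in erythroid progenitor-like cells (−0.59). Shares that reversed there were the neutrophil-like share of all cells (0.29), the granulocyte-monocyte progenitor-like share of all cells (−0.050) and the neutrophil-like share of the stages (0.38). The part of a class that carries Xist differed between classes and groups, so this selection can itself turn these shares. Lists that reversed there, with adjusted p, were immediate early (0.595) and glycolysis (0.574) in neutrophil-, MHC class II in monocyte- (0.139), G2 and M phase (0.0371) and mitochondrially encoded (0.619) in mature B- and megakaryocyte in megakaryocyte progenitor-like cells (0.529), and G2 and M phase in the Irf8 and F13a1 cluster (0.725). With low-UMI clusters kept, the granulocyte-monocyte progenitor-like share of all cells (−0.11) and the precursor stage share (0.022) reversed.

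With each library left out in turn, the counts ran from 31 to 296 (stem and multipotent), 54 to 142 (granulocyte-monocyte progenitor), 10 to 19 (neutrophil), 20 to 56 (monocyte), 7 to 68 (erythroid), 2 to 35 (mature B), 7 to 45 (megakaryocyte), 17 to 88 (all cells) and 24 to 200 (Irf8 and F13a1 cluster). The tests between adjacent classes gave 0 to 175, 4 to 19 and 0 to 2 genes. The precursor stage share ran from −0.27 to 0.014, 0 to 1 shares of all cells passed and 0 to 3 stage shares. Adjusted p of lists that reversed ran from 6.3e-32 to 0.191 (G2 and M phase, stem and multipotent), 3.1e-15 to 0.749 (MHC class II, stem and multipotent), 5.1e-38 to 0.900 (immediate early, stem and multipotent), 3.3e-20 to 0.660 (ribosomal, neutrophil precursor), 4.4e-09 to 0.289 (ribosomal, neutrophil), 2.8e-12 to 0.445 (primary granule, erythroid), 8.5e-58 to 0.174 (secondary granule, erythroid), 1.9e-11 to 0.792 (G2 and M phase, mature B), 0.000400 to 0.828 (G2 and M phase, Irf8 and F13a1 cluster) and 4.1e-17 to 0.0388 (B cell, all cells). Not run were all cells summed at the higher resolution, with a class per cell, with equal cell numbers and with low-UMI clusters kept, the Irf8 and F13a1 cluster with 300 UMIs, at the higher resolution and with a class per cell, and dendritic cell-like cells among Xist-carrying cells.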

Other observations

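Among cells with UMIs of Xist or of Y-linked genes but not of both, the share with Xist was 92.7% and 73.3% in Idh1-WT and 67.6% and 55.1% in Idh1-R132H. Cells with UMIs of both, which this share leaves out, numbered 72 and 108 in Idh1-WT and 193 and 229 in Idh1-R132H. The labels do not state the sex of donors or recipients. Whether cells of either sex come from donor or recipient, and so carry the labelled genotype, cannot be told.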
